A study of Homo sapiens with 12 samples.

How the data were processed

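RNA sequencing libraries of human CD4+ T cells were analysed from the deposited processed files alone. Per the labels, CD4+ cells were positively selected from peripheral blood, rested for 72 h with IL-2 (40 IU/mL), loaded with 1 µM CFSE and stimulated with anti-CD3 (5 µg/mL), anti-CD28 (1 µg/mL) and PDL1 or PDL2 (5 µg/mL). Cells were then sorted by CFSE signal, and total RNA went into an ultra-low-input library; whether it was selected by poly(A) is not stated. The 12 libraries fall into 4 groups of 3: PDL1 proliferating, PDL1 non-proliferating, PDL2 proliferating and PDL2 non-proliferating. The labels give each library a donor, and each of the 3 replicate numbers stands for 1 donor in all groups.

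Each library has 1 file with 48104 RefSeq transcripts of 25678 gene symbols. The counts deposited by the authors are whole numbers of reads per transcript, without normalization. The FPKM values deposited by the authors are those counts per kilobase of transcript, scaled to the summed transcript counts of the library. The TPM values deposited by the authors are scaled to the same sum over transcripts in each library. Per the submitters' processing notes, reads were aligned with STAR to hg19 and DESeq2 was used; their versions are not given in the sources used here, and neither are the read counter, its strand setting and its filters. FPKM and TPM entered no test.

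Isoforms of a gene held nearly equal counts (median ratio of the second to the first 0.998 over 4255 genes), as if a shared read had been counted for each isoform, which the sources used here do not state. Transcripts were therefore not added up: each gene was represented by 1 transcript, chosen by total count, which applied to 9491 genes with more than 1. Y-linked genes, XIST and TSIX (109 symbols) were left out, which left 25569 genes. Gene counts per library then totalled 26914713 to 60491527. The mitochondrial genome's genes are not in the files. Among the genes tested, 21 symbols had been turned into dates and were not named.

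Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group (16038 genes), and a quasi-likelihood F-test with robust estimation in 1 fit of the 4 groups. The comparisons were proliferating against non-proliferating under each ligand and as the mean of both, the difference of that effect between ligands, and PDL2 against PDL1 in each sorted fraction. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The same fit with the replicate number as a block was run beside each comparison, since each donor gave 1 library to each group. Expression is given as CPM with TMM-scaled library sizes, as mean and SD over libraries.

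Gene lists (39, of which 38 had at least 3 genes tested) were written for this cell type: cell cycle phases, quiescence, histones, T cell activation, inhibitory receptors, PD-1 and T cell receptor signalling, memory and helper subsets, cytokines, cytokine responses, metabolism, ribosomes, stress, apoptosis, and markers of other blood cells. Their 14 genes absent from the files were dropped. Each list was tested with camera (limma 3.58.1, preset correlation 0.01) against the other genes, and again with the correlation estimated and with fry. Counts of list members are given over all genes and adjusted over the list alone. Named genes were, for the mean of both ligands, the 12 largest changes each way among genes that passed, with the same sign in all 6 same-donor differences and at least 10 CPM in the higher state. The other comparisons took 5 each way by the same rule, and each list its first 4 members and up to 4 more that passed. T cell receptor and immunoglobulin segments, genes present or absent by donor, pseudogenes and read-through genes were not named. Groups, tests, lists and this rule were fixed before the data were examined.

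Alternatives were the replicate block, DESeq2 1.42.0, limma-voom, DESeq2 size factors, no low-count filter, a filter of 5 CPM in 3 libraries, a minimum change of 1.5-fold (glmTreat), and leaving out each library and each replicate number. Sums of both ligands per donor, sums of transcripts per gene, and a fit without the non-proliferating libraries of replicate 1 were also run. The trend of fold changes with transcript length, GC content and expression was estimated by splines with 4 degrees of freedom on 15719 genes with a known GC content (98%).

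The power of the design was tested on simulated data, 200 changed genes among 15650. For the mean of both ligands the fit without the block recovered 0% of 2-fold and 38% of 4-fold changes, with 38 calls and 0 false ones. With the block it recovered 50% and 78%, with 5 false calls among 133. For PDL1 alone the block recovered 17% and 60%, with 7 false calls among 84, and for PDL2 16% and 63%, with 8 among 87. Without the block at most 2% of 4-fold changes were recovered for a single ligand. The simulated change of a gene was the same in every donor, and libraries of a donor varied independently. Where changes differ between donors, recovery and false calls may be less favourable. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3, numpy 2.4.6 and Python 3.11.15.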

Results

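Gene expression was measured by RNA sequencing in 12 libraries of human CD4+ T cells from the blood of 3 donors. The cells were loaded with CFSE, a dye that is diluted at each division, and cultured with anti-CD28 on a surface coated with anti-CD3 and either PDL1 or PDL2, the ligands of the inhibitory receptor PD-1. They were sorted by CFSE signal into proliferating and non-proliferating cells, which gave 4 groups of 3 libraries. Cells stimulated without a PD-1 ligand were not analysed here, so no comparison isolates the effect of the ligands. The gene count per library ranged from 26914713 to 60491527, and replicate 1 of the PDL2 non-proliferating group was the shallowest. Replicate 1 stood apart from replicates 2 and 3 in every group: over 9403 genes the median absolute log2 difference between them was 2.65 to 4.63 times that between replicates 2 and 3. Replicate numbers follow the donors in the labels. Without the replicate block p-values measure the spread of libraries within groups of 3 donors. With the block they measure the spread left after donor means are taken out. The average over ligands treats the PDL1 and PDL2 libraries of a donor as separate, although they share that donor.

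The main question was how T cells that divided under PD-1 ligation differed from those that did not. Averaged over both ligands, proliferating cells expressed more E2F2, CLSPN, ASPM and PTTG1, genes of DNA replication and mitosis, and more LGALS1, CD38, CCR2 and CD58, genes of activated and effector T cells. They expressed less IFIT2, GBP6 and GBP1, which are induced by interferon, less BACH2, a transcription factor of resting lymphocytes, less CD274, which encodes PDL1 itself, and less PTK2, the focal adhesion kinase. LGALS1 stood at 586 ± 337 CPM (SD, n = 6) in proliferating and 115 ± 57.8 CPM in non-proliferating libraries, and IFIT2 at 10.9 ± 5.66 CPM against 260 ± 219 CPM. By edgeR's quasi-likelihood test 211 of 16038 genes changed at an adjusted p under 0.05, 69 upward and 142 downward. With the replicate block, which compares cells of the same donor, 3486 genes changed, 1830 upward and 1656 downward, among them all 211. Among these, 634 rose and 889 fell by at least 2-fold in the fitted change. When both ligands were summed per donor the block gave 901 genes, 200 of the 211 among them, and the test without the block gave 0, with 1093 at an unadjusted p under 0.05. Leaving out any 1 of the 12 libraries left 14 to 134 genes without the block.

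The 12 genes with the largest increase among the 211 were NPTX1, APOD, C12orf75, LGALS1, CDKN2A, RAMP1, E2F2, MYO1F, CD38, CCR2, KIAA0101 and TOR4A, with log2 fold changes from 3.26 to 2.11. NPTX1 (NM_002522), a neuronal pentraxin, rose by 3.26 ± 0.60 on the log2 scale (SE, adjusted p = 0.0334), from 8.90 ± 5.93 to 91.2 ± 78.5 CPM. C12orf75 (NM_001145199) rose by 2.45 ± 0.31 (adjusted p = 0.00823), from 76.2 ± 24.1 to 409 ± 130 CPM. LGALS1 (NM_002305), galectin-1, rose by 2.39 ± 0.45 (adjusted p = 0.036), and the myosin gene MYO1F (NM_012335) by 2.22 ± 0.43 (adjusted p = 0.0371), from 60.7 ± 32.6 to 287 ± 116 CPM. CD38 (NM_001775), an enzyme on the surface of activated T cells, went from 30.2 ± 15.3 to 138 ± 26.3 CPM (adjusted p = 0.0328). CCR2, a chemokine receptor, went from 23.9 ± 13.4 to 109 ± 69.1 CPM (adjusted p = 0.0496). E2F2, a transcription factor of S phase entry, went from 18.1 ± 4.87 to 91.1 ± 50.1 CPM (adjusted p = 0.0244), and CDKN2A, an inhibitor of cyclin-dependent kinases, from 7.98 ± 2.60 to 42.1 ± 31.7 CPM (adjusted p = 0.0477).

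The 12 largest decreases were in WWC2, SCML1, WNT10A, ZNF629, IFIT2, GBP6, AMIGO1, APBA2, PTK2, ZNF540, PLEKHB1 and ZNF844, with log2 fold changes from -9.25 to -3.21. PTK2 (NM_001199649) had the lowest adjusted p of all genes (0.00264) and fell by 3.73 ± 0.34 on the log2 scale, from a mean of 20.1 ± 6.08 CPM. GBP6 (NM_198460), a guanylate-binding protein gene, fell from 16.7 ± 5.46 to 0.739 ± 0.491 CPM (adjusted p = 0.00475), and WNT10A, which encodes a secreted Wnt ligand, from 11.1 ± 3.31 to 0.232 ± 0.146 CPM (adjusted p = 0.0134). PLEKHB1 (NM_001130034), a pleckstrin homology domain gene, fell by 3.24 ± 0.34 (adjusted p = 0.00475), to 4.52 ± 0.56 CPM. APBA2, an adaptor of the amyloid precursor protein, fell by 3.89 ± 0.59 (adjusted p = 0.0157), to 2.48 ± 2.45 CPM. The fold of WWC2 rests on 6 reads in all proliferating libraries together, against 2745 in the non-proliferating ones. ZNF629, ZNF540 and ZNF844 encode zinc finger proteins. The rule that chose these 24 genes required the same direction in all 6 same-donor comparisons.

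**Figure D1:**
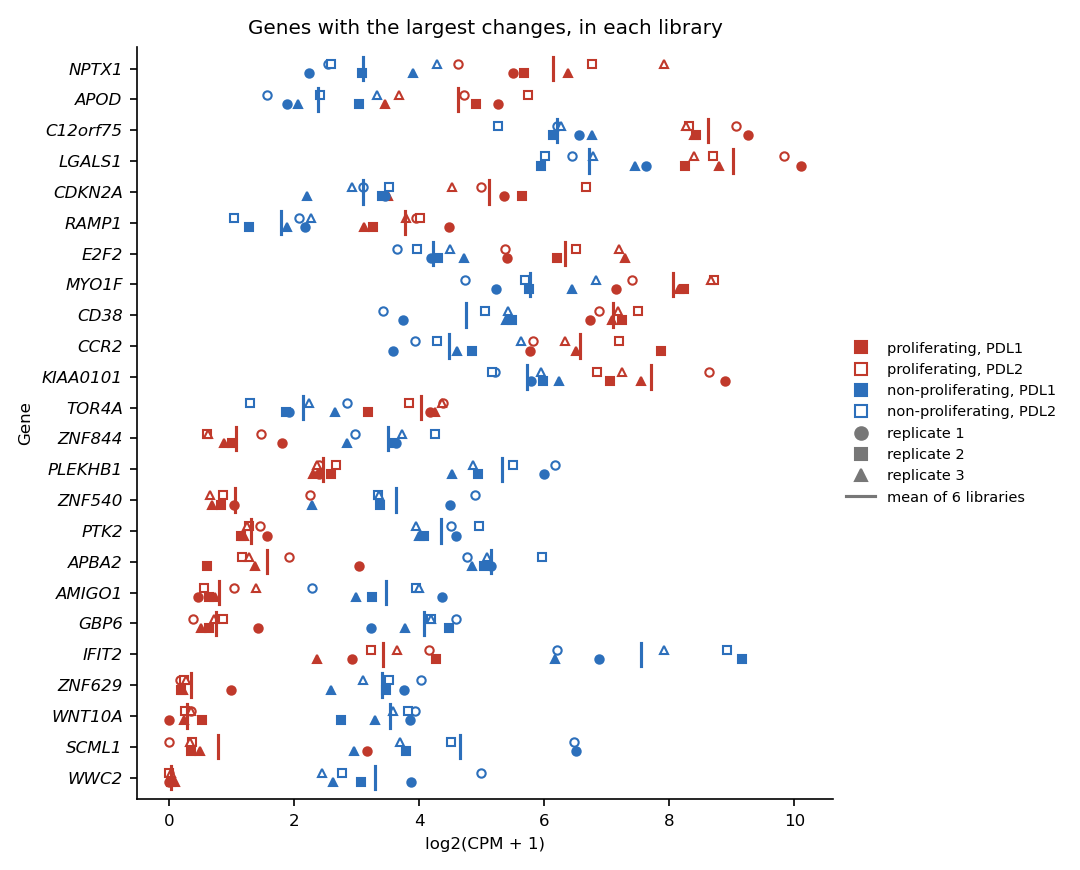
Expression of the 24 genes with the largest changes averaged over both ligands, as log2(CPM + 1) in each of the 12 libraries, with marker shape for the replicate, colour for the sorted fraction, filling for the ligand and a line at the mean of 6 libraries. Genes run from NPTX1, with a log2 fold change of 3.26, at the top to WWC2, with -9.25, at the bottom.

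Of 41 genes of G2/M and mitosis, 4 rose over all genes tested, 13 adjusted over the list alone and 40 with the replicate block, with a median log2 fold change of 1.25. MKI67, a marker of cycling cells, was at 377 ± 142 CPM in proliferating and 124 ± 90.2 CPM in non-proliferating libraries (log2 fold change 1.61, adjusted p = 0.167, with the block 0.00204). ASPM, a spindle gene, rose by 1.66 ± 0.33 (adjusted p = 0.0396), and PTTG1, the securin gene, by 2.06 ± 0.44 (adjusted p = 0.049). Of 48 genes of G1/S and DNA replication, 2 rose over all genes, CLSPN and E2F2, 2 adjusted over the list alone and 40 with the block, with a median of 0.88. RRM2, a subunit of ribonucleotide reductase, was at 931 ± 498 against 401 ± 286 CPM (with the block, adjusted p = 0.00246). The replication-dependent histone genes had a median of 1.89 over 38 genes, and 0 passed over all genes, 10 adjusted over the list alone and 14 with the block. Camera, which ranks a list against the other genes, gave adjusted p = 3.02e-22 for G2/M, 1.39e-12 for G1/S and 2.48e-15 for the histones. With an estimated correlation these were adjusted p = 0.353, 0.611 and 0.353. In replicate 1 the median of the G1/S list was lower than in replicates 2 and 3 in every group, with log2 differences from -2.39 to -1.56. Non-proliferating cells still contained cell cycle transcripts: TOP2A, a topoisomerase of dividing cells, was at 244 ± 160 CPM there and 535 ± 102 CPM in proliferating cells. These transcripts differed between donors. In non-proliferating cells the G2/M median of replicate 1 differed from replicates 2 and 3 by -2.37 (PDL1) and -2.17 (PDL2) on the log2 scale. The same-donor G2/M medians under PDL1 and PDL2 were 2.64 and 2.82 in replicate 1, 1.06 and 1.69 in replicate 2, and 0.54 and 0.89 in replicate 3.

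Inhibitors of the cell cycle went both ways. Among 21 such genes 2 rose and 2 fell over all genes tested, 2 and 5 adjusted over the list alone, and 3 rose and 8 fell with the block, with a camera adjusted p = 0.0657, with the block 0.0141, and 0.62 with an estimated correlation. CDKN2A and CDKN2C rose, the latter from 20.3 ± 4.08 to 50.7 ± 12.1 CPM (adjusted p = 0.0249). PIK3IP1, an inhibitor of PI3 kinase, fell from 353 ± 129 to 94.0 ± 41.3 CPM (adjusted p = 0.036), and BTG2, an antiproliferative gene, from 243 ± 31.9 to 120 ± 15.3 CPM (adjusted p = 0.0443).

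Of 22 naive and central memory genes 1 fell over all genes, BACH2, from 86.1 ± 32.7 to 22.5 ± 12.2 CPM (adjusted p = 0.0443). Adjusted over the list alone 1 rose and 7 fell, and with the block 3 rose and 11 fell. With the block IL7R, the interleukin 7 receptor, fell from 752 ± 780 to 106 ± 122 CPM (adjusted p = 9.4e-05), TCF7, a transcription factor of stem-like T cells, from 338 ± 226 to 105 ± 138 CPM (adjusted p = 0.00268), and CCR7, the lymph node homing receptor, from 935 ± 264 to 422 ± 103 CPM (adjusted p = 0.00218). Of 20 effector memory genes 3 rose over all genes, 4 adjusted over the list alone and 12 with the block. They included PRDM1, which encodes the regulator BLIMP-1 (93.4 ± 28.7 to 223 ± 38.8 CPM, adjusted p = 0.046), and CD58, an adhesion molecule (44.2 ± 15.4 to 130 ± 51.9 CPM, adjusted p = 0.036). Camera gave adjusted p = 0.00263 for the naive and 3.15e-05 for the effector memory list, and adjusted p = 0.353 for both with an estimated correlation.

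Activation markers and inhibitory receptors differed between replicates. The median same-donor log2 difference of the inhibitory receptors was 0.59 to 0.90 in replicates 1 and 2, and -0.18 under PDL1 and -0.31 under PDL2 in replicate 3. That of the activation markers was 0.62 to 1.20 in replicates 1 and 2, and -0.07 and 0.09 in replicate 3. Of 19 activation markers 1 rose (CD38) and 1 fell (CD69) over all genes, 3 and 2 adjusted over the list alone, and 9 rose and 2 fell with the block (camera adjusted p = 0.0198, adjusted p = 0.728 with an estimated correlation). CD69, an early activation marker, fell by 1.39 ± 0.27 on the log2 scale (adjusted p = 0.036), to 78.8 ± 9.32 CPM, while IL2RA, the interleukin 2 receptor alpha chain, rose with the block only, from 617 ± 436 to 1001 ± 604 CPM (adjusted p = 0.0185). Of 16 inhibitory receptor genes 2 rose over all genes, 4 adjusted over the list alone and 6 with the block (camera adjusted p = 0.0106, adjusted p = 0.353 with an estimated correlation). These were ENTPD1, the ectonucleotidase CD39 (log2 fold change 1.55 ± 0.25, adjusted p = 0.0212), and LAIR1, a collagen receptor (21.1 ± 3.40 to 68.7 ± 25.2 CPM, adjusted p = 0.0167). With the block HAVCR2, the TIM-3 gene, rose (log2 fold change without the block 1.81 ± 0.58, adjusted p = 0.154, with it 0.000286) and LAG3 from 81.6 ± 43.8 to 142 ± 45.3 CPM (adjusted p = 0.00282). PDCD1, which encodes PD-1, was at 44.9 ± 16.4 and 31.8 ± 24.5 CPM and did not pass (with the block, adjusted p = 0.0566). Of 16 genes of PD-1 signalling 1 fell over all genes, 3 rose and 2 fell adjusted over the list alone, and 6 rose and 2 fell with the block (camera adjusted p = 0.243, adjusted p = 0.728 with an estimated correlation). CD274 fell by 1.62 ± 0.27 on the log2 scale (adjusted p = 0.0232), to 15.9 ± 2.96 CPM. PTPN11, the SHP-2 phosphatase gene, rose with the block from 102 ± 29.7 to 167 ± 23.2 CPM (adjusted p = 0.00612). Of 23 genes of T cell receptor signalling 0 passed without the block in edgeR, and 7 rose and 3 fell with it (camera adjusted p = 0.678). LCK, the kinase at the receptor, was at 1120 ± 374 and 730 ± 185 CPM (with the block, adjusted p = 0.00719). Of 22 immediate early genes 0 passed over all genes, 1 rose and 2 fell adjusted over the list alone, and 2 rose and 4 fell with the block (camera adjusted p = 0.544). NR4A1, induced by receptor signals, was at 36.8 ± 19.3 and 82.4 ± 50.3 CPM (with the block, adjusted p = 0.00458).

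Interferon response genes were lower in proliferating cells. Of 26 genes 2 fell over all genes, 10 adjusted over the list alone and 14 with the block, and 0 rose in any of these counts (median log2 fold change -0.83, camera adjusted p = 3.75e-08, adjusted p = 0.481 with an estimated correlation). IFIT2 fell by 4.58 ± 0.70 (adjusted p = 0.0157) and GBP1 by 1.52 ± 0.32 (adjusted p = 0.046). MX1 and ISG15, also induced by interferon, were near equal, at 390 ± 237 and 355 ± 228 CPM for MX1 and 240 ± 92.8 and 295 ± 142 CPM for ISG15. Of markers of other cells in these libraries, the dendritic cell gene LAMP3 fell by 2.17 ± 0.40 on the log2 scale (adjusted p = 0.0345), while the monocyte gene LYZ rose with the block from 4.82 ± 5.71 to 25.5 ± 29.2 CPM (adjusted p = 0.00314). With the block the list of dendritic cell markers had a camera adjusted p = 0.0331 (adjusted p = 0.278 with an estimated correlation). Of 20 hypoxia genes 2 fell over all genes, BNIP3 and MXI1, and 5 adjusted over the list alone or with the block (camera adjusted p = 0.0108, adjusted p = 0.481 with an estimated correlation). MXI1, a MYC antagonist, fell from 75.2 ± 22.3 to 17.5 ± 5.32 CPM (adjusted p = 0.011).

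Of 53 nuclear genes of oxidative phosphorylation 0 passed over all genes or adjusted over the list alone by edgeR, and 42 rose with the block (median log2 fold change 0.62, camera adjusted p = 4.06e-08, adjusted p = 0.481 with an estimated correlation). ATP5B, an ATP synthase subunit, was at 1528 ± 711 against 1014 ± 591 CPM (with the block, adjusted p = 0.0126). The median of this list was 0.23 after the trend of the fold changes with transcript length, GC content and expression was taken out. The same step took the medians of the tricarboxylic acid cycle from 0.42 to 0.26, fatty acid oxidation from 0.32 to 0.09, the unfolded protein response from 0.23 to 0.15, the activation markers from 0.59 to 0.38 and the cytosolic ribosomal proteins from -0.28 to -0.77. Of 20 genes of the tricarboxylic acid cycle 0 passed without the block and 9 rose with it (median 0.42, camera adjusted p = 0.0198, adjusted p = 0.758 with an estimated correlation). The 72 cytosolic ribosomal protein genes had a median of -0.28, and 18 fell with the block (camera adjusted p = 0.258, with the block 4.51e-05, and with the block adjusted p = 0.48 with an estimated correlation). The same genes were higher in replicate 1 than in replicates 2 and 3, by median log2 differences of 2.08 to 2.44. For glycolysis, 1 of 24 genes fell over all genes, ALDOC, and 6 rose and 3 fell with the block (camera adjusted p = 0.597). Lists of fatty acid oxidation, cholesterol and fatty acid synthesis, serine and amino acid supply, ribosome biogenesis, the unfolded protein response and heat shock had camera adjusted p-values of 0.0596, 0.243, 0.959, 0.959, 0.247 and 0.983. With the block the first and the unfolded protein response had 0.0432 and 0.0331, both lost with an estimated correlation (adjusted p = 0.278). DDIT3, a stress-induced transcription factor in the serine list, fell from 87.1 ± 33.8 to 31.7 ± 7.96 CPM (adjusted p = 0.0451) and was the only member of these 6 lists to pass over all genes.

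Camera called 11 of 38 lists in this comparison, 17 with the block and 0 with an estimated correlation. As many lists as the 11 were called in 59 of 100 splits of the libraries. Most of these splits, unlike the real one, leave both sorted fractions of some donor in the same group. With the block, where every split keeps these fractions apart, 4 of 32 splits (the real one included) called as many as the real 17. The camera p-values alone thus did not set these lists apart.

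**Figure D2:**
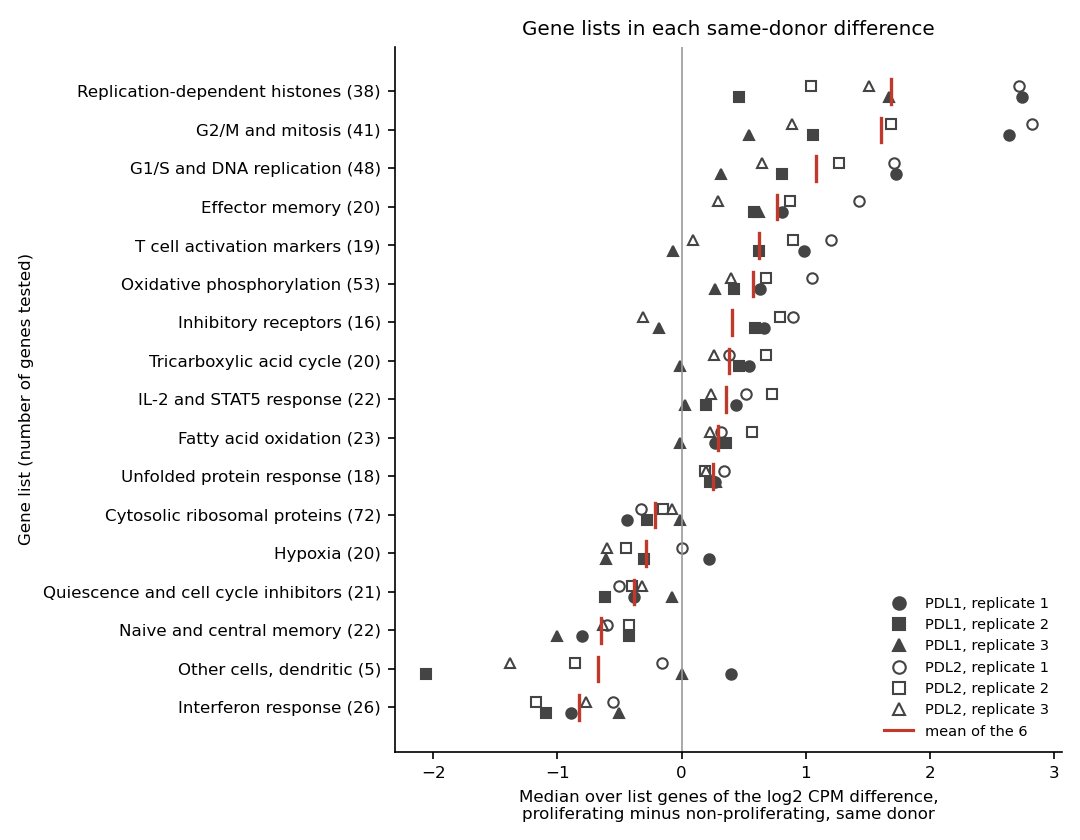
Median over the genes of each list of the log2 CPM difference between proliferating and non-proliferating cells of the same donor, for 17 lists called by camera with or without the replicate block, with marker shape for the replicate, filling for the ligand and a red line at the mean of the 6 values. All 6 values lie above 0 for G2/M and mitosis and below 0 for the interferon response.

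Over all genes tested, 0 of 12 Th1, 0 of 16 Th17 and 0 of 13 follicular helper genes passed in edgeR, and with the block 3 Th1 genes rose and 1 fell, 1 Th17 gene rose and 2 fell, and 4 follicular helper genes rose and 3 fell. STAT6, a transducer of interleukin 4 signals, fell from 227 ± 40.6 to 106 ± 17.8 CPM (adjusted p = 0.0443) and was the only 1 of 15 Th2 genes to pass, against 6 with the block. With the block the Th1 receptor CXCR3 rose from 52.6 ± 25.6 to 167 ± 26.9 CPM (adjusted p = 0.0144), while BCL6 (41.1 ± 28.3 to 7.50 ± 6.26 CPM, adjusted p = 0.000447) and CXCR5 (30.7 ± 10.9 to 9.86 ± 5.00 CPM, adjusted p = 0.00517), both of follicular helper cells, fell. The lineage regulators TBX21 (44.9 ± 25.8 and 47.1 ± 29.9 CPM) and FOXP3 (log2 fold change 0.32 ± 0.61) did not pass in either fit. Among cytotoxic genes PRF1, which encodes perforin, rose with the block from 70.5 ± 48.6 to 169 ± 51.4 CPM (adjusted p = 0.00815), and GZMB, granzyme B, was at 979 ± 774 and 1311 ± 1613 CPM. Camera adjusted p-values for the Th1, Th2, Th17, follicular helper, regulatory and cytotoxic lists were 0.463, 0.313, 0.983, 0.959, 0.0729 and 0.0545. Adjusted over the list alone, 2 Th1 and 6 follicular helper genes passed, 2 Th2 genes, 1 regulatory and 1 cytotoxic gene, and 0 of Th17. The cytokine and chemokine list had a median of 0.11, a mean of -0.25 and a camera adjusted p = 0.95, and those of interleukin 2 and STAT5 response, apoptosis and p53 targets had 0.114, 0.465 and 0.874. With the block the interleukin 2 list had 0.0164 (adjusted p = 0.278 with an estimated correlation), and PIM1, a kinase gene induced by interleukin 2, rose from 152 ± 33.5 to 311 ± 116 CPM (adjusted p = 0.00148). Markers of CD8 T and NK cells, B cells, monocytes, dendritic cells, and platelets and erythroid cells had camera adjusted p-values of 0.95, 0.544, 0.983, 0.119 and 0.95. With the block 2 of the 5 dendritic cell genes fell, LAMP3 and CD83, the latter chosen after its values were seen.

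Each ligand was then taken alone. Under PDL1, 0 of 16038 genes passed edgeR without the block, with 860 at an unadjusted p under 0.05, 268 called by DESeq2 and 0 by limma-voom. With the replicate block 180 genes rose and 263 fell, among them PTK2, C12orf75, CD38, IFIT2 and GBP6. Under PDL2, 0 genes passed without the block, with 1596 at an unadjusted p under 0.05, 734 called by DESeq2 and 0 by limma-voom, and with the block 885 rose and 789 fell. NPTX1 stood at 58.7 ± 20.4 against 8.35 ± 5.13 CPM under PDL1 (SD, n = 3) and at 124 ± 109 against 9.44 ± 7.79 CPM under PDL2. CCR7, the homing receptor, stood at 405 ± 93.8 against 1011 ± 128 CPM under PDL1 and at 440 ± 130 against 859 ± 376 CPM under PDL2. All 443 genes called under PDL1 with the block had the same sign under PDL2. The calls of both ligands shared 173 higher and 252 lower genes, where independent lists of those sizes would share 9.9 and 12.9. Neither these expected values nor the correlation below takes into account that both ligands share the same 3 donors. Across 9403 genes of at least 10 CPM, which are not independent replicates, the log2 fold changes under the ligands had a Pearson r of 0.877 and a Spearman rho of 0.85. Blocked counts depended on single libraries. The PDL1 count was 0 without the PDL1 proliferating library of replicate 2 and 1213 without the PDL2 non-proliferating library of replicate 1. The PDL2 count was 176 without the PDL2 proliferating library of replicate 2.

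**Figure D3:**
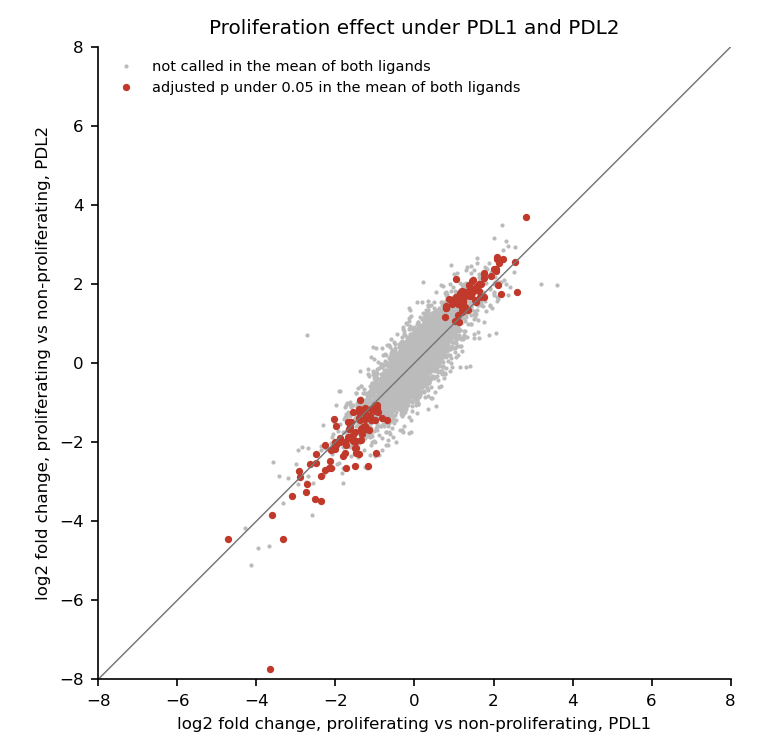
Log2 fold change of proliferating against non-proliferating cells under PDL1 (horizontal axis) and PDL2 (vertical axis) for 9403 genes of at least 10 CPM, 1 point per gene, with the line of equal change. Red points are the 151 of these genes that passed in the average over both ligands, a choice that favours genes far from 0 in that average.

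The last comparisons asked whether PDL1 and PDL2 differed. For a different response to proliferation under the ligands, edgeR called 0 genes with 97 at an unadjusted p under 0.05, and 0 with the block with 155. Limma-voom called 0 genes, DESeq2 called 1 and DESeq2 with the block 222. MKI67 was at 385 ± 161 and 137 ± 97.3 CPM in proliferating and non-proliferating cells under PDL1 (SD, n = 3) and at 370 ± 155 and 111 ± 102 CPM under PDL2. By camera the G2/M list (median difference of log2 fold changes 0.41, adjusted p = 0.00772) and the oxidative phosphorylation list (0.33, adjusted p = 0.00581) had a larger difference under PDL2, and both had adjusted p = 0.976 with an estimated correlation. Without replicates 1, 2 and 3 camera called 9, 0 and 2 lists here. The median of the oxidative phosphorylation list was -0.01 after the trend with length, GC content and expression was taken out.

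Between the ligands, 0 genes passed edgeR in proliferating cells, with 43 at an unadjusted p under 0.05 and 166 with the block, which also called 0. In non-proliferating cells 0 passed with 200, and 0 with 777 in the block. Limma-voom called 0 in both, DESeq2 4 and 2, and DESeq2 with the block 206 and 383. The cytokine and chemokine list was lower under PDL2 than under PDL1 by camera, with a mean log2 difference of -0.89 over 26 genes in proliferating cells (adjusted p = 3.87e-10, adjusted p = 0.415 with an estimated correlation) and -0.81 in non-proliferating cells (adjusted p = 0.00384, adjusted p = 0.673 with an estimated correlation). None of its genes passed over all genes or adjusted over the list alone. A mean can rest on a few genes with large changes. In the proliferation comparison the mean and median of this list had opposite signs, so these means do not show whether a typical member was lower. IFNG, the interferon gamma gene, was at 60.5 ± 34.7 CPM under PDL2 and 120 ± 19.5 CPM under PDL1 in proliferating cells (SD, n = 3), and CSF2, which encodes GM-CSF, at 91.1 ± 59.2 and 185 ± 89.2 CPM. In non-proliferating cells the G2/M list was lower under PDL2 (median -0.56, camera adjusted p = 1.38e-06, adjusted p = 0.673 with an estimated correlation). Camera called 8 lists in proliferating and 12 in non-proliferating cells, 15 and 13 with the block, and 0 with an estimated correlation in either fit. On leaving out a replicate number these counts ran from 1 (without replicate 3) to 15 (without replicate 1) in proliferating and from 5 (without replicate 2) to 17 (without replicate 1) in non-proliferating cells.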

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

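The tests of other-cell markers against the interferon genes were chosen after the result was seen. The other tests here had their bounds written before, but the bound for the histone genes in replicate 1 was not applied.

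The libraries of replicate 1 stood apart from replicates 2 and 3 in all 4 groups. They had higher MALAT1 (log2 differences 2.86 to 3.63) and NEAT1 (5.26 to 6.60), nuclear RNAs, higher ribosomal protein genes (2.08 to 2.44) and lower G1/S genes (-2.39 to -1.56). A few dominant genes were argued against, because the median absolute log2 difference over 9403 genes was at least 2.65 times that between replicates 2 and 3. Length and GC content explained 17.8% and 20% of the variance across genes in the proliferating groups (PDL1, PDL2), against 16.8% and 17.9% between replicates 2 and 3, and 10.8% and 8.1% in the non-proliferating groups, against 3.7% and 2.2%, so such a bias stays open. More nuclear or non-polyadenylated RNA could raise histone genes, but their lowest difference was -0.87 (PDL2 non-proliferating) and the highest 1.55. By the bound written before, the low values in the non-proliferating groups would argue against this explanation. That bound was not applied, because S phase genes were lower too in every group. More such RNA thus cannot be told apart from a difference in cycling. Donor and library batch are confounded for these libraries, and a donor difference was not tested.

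By the test of the difference between ligands, the G2/M list (camera adjusted p = 0.00772, median 0.41) and the oxidative phosphorylation list (adjusted p = 0.00581, median 0.33) had a larger proliferation effect under PDL2, and both had adjusted p = 0.976 with an estimated correlation. For G2/M the shallow PDL2 non-proliferating library of replicate 1 was argued against as the cause, since replicates 2 and 3 gave 0.65 and 0.35. A trend with length, GC content and expression was also argued against, with 89.4% of the median left. For oxidative phosphorylation the shallow library cannot be told apart (0.25 and 0.1 in replicates 2 and 3). A trend with length, GC content and expression may account for the difference, with -2.9% left (0.33 before, -0.01 after). These were taken out together, so the test does not tell length and GC content from expression. The lists called between ligands were as many in 94 of 100 splits (2 in the real split, 19 at most in another). Many of these splits, unlike the real one, give the ligands unequal shares of the donors, so they cannot decide about chance. Chance is thus not excluded, and the difference between PDL1 and PDL2 stays an untested biological explanation for G2/M.

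Interferon response genes were lower in proliferating libraries (median log2 fold change -0.83). B cells or monocytes in the non-proliferating gate were argued against by their 7 markers of at least 1 CPM, with a median fitted log2 change of 0.65 (MAD 0.62, 1 of 7 lower) and a median log2 ratio of mean CPM of 0.62 (MAD 0.95, 3 of 7 lower, VCAN from 2.18 to 0.127 CPM); LYZ, abundant in monocytes, was at 4.82 CPM in non-proliferating and 25.5 CPM in proliferating libraries. Dendritic cells in that gate cannot be told apart, since their 4 markers of at least 1 CPM had a median of -0.49 (MAD 0.84, 3 of 4 lower) and went apart: LAMP3 -2.17, CD83 -0.92, CCL17 -0.06 and FSCN1 0.21. The libraries of replicate 1 were argued against as the source, since the value nearest 0 in replicates 2 and 3 was -0.5. A trend with length, GC content and expression was also argued against, with 113.7% of the median left. Dendritic cells and a difference in interferon exposure or response between dividing and undivided cells, which was not tested, stay open.

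For the genes called in the mean of both ligands 3 of 100 splits without the block (of 200 possible) gave as many as the real 211. The others gave 1579 and 360 and part only 2 of the 6 donor pairs, as many splits with 0 calls also do. Whether the replicate numbers account for these counts was not tested. With the replicate block 1 of 32 splits gave as many as the real 3486, and the highest other gave 0. Most splits without the block part fewer than 6 donor pairs, unlike the real one. The 3 of 100 is thus not a share over like groupings and cannot exclude chance. The share with the block excludes chance only if the PDL1 and PDL2 libraries of a donor vary apart from each other. Exchanging the sorted fractions of whole donors allows 4 splits, too few for a share under 0.05. For the lists called, 59 of 100 splits gave as many as the real 11 (highest other 19). Most of these part fewer than 6 donor pairs, unlike the real one, so the 59 is not a share over like groupings. With the block, where every split parts all 6 pairs, 4 of 32 gave as many as 17 (highest other 21), so chance was not excluded. For the difference between ligands 100 of 100 splits gave at least the real 0 genes (highest other 1873). Any split must give at least 0, so this share and those below for a real count of 0 decide nothing. Each single comparison has only 10 splits, too few for a share under 0.05. Without the block 10 of 10 gave as many as the real 0 under PDL1, under PDL2 and in both PDL2 vs PDL1 comparisons (highest other 0). With the block 1 of 10 gave as many as the real 443 under PDL1 and 1674 under PDL2, and 10 of 10 as many as the real 0 in both PDL2 vs PDL1 comparisons (highest other 0).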

How the results depend on the processing

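Transcripts summed per gene, all fits without the non-proliferating libraries of replicate 1, and the alternatives tried on the blocked fits were chosen after the data were seen. The mean of both ligands (211 genes) gave 1594 with DESeq2, 140 with no low-count filter, 36 with a minimum change of 1.5-fold, 3486 with the replicate block, 901 with ligands summed per donor and blocked, and 0 summed without the block (edgeR, 1093 at an unadjusted p under 0.05). Leaving out replicates gave 0 (without replicate 2, or without replicate 3) to 3066 (without replicate 1, all 211 shared). PDL1 (0) gave 268 with DESeq2, 443 with the replicate block, 1 with transcripts summed (PTK2) and 0 to 180 on leaving out replicates (180 without replicate 1). PDL2 (0) gave 734 with DESeq2, 1674 with the replicate block, 6 with the strict filter (BBS2, GBP6, PTK2, SGK3, TRIM44 and ZNF441), 1 with transcripts summed (PTK2), 3 without both non-proliferating libraries of replicate 1 (PLEKHB1, PTK2 and RASGRP2) and 0 to 1163 on leaving out replicates (1163 without replicate 1). Genes in these small counts outside the naming rule were chosen after their values were seen. DESeq2 called 1 gene in the difference between ligands (DLGAP1-AS5), 4 in PDL2 vs PDL1 in proliferating cells (DLGAP1-AS5, LIMCH1, POU5F1B and SLC22A7) and 2 in non-proliferating cells (DLGAP1-AS5 and EGFEM1P). Their fitted log2 fold changes, from -19.84 to 42.34, lie outside any range these counts can measure. DESeq2 with the block called 222, 206 and 383 genes in these 3 comparisons, against 0 by edgeR and limma-voom with the block. The cause of these differences was not tested.

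With the replicate block, the mean of both ligands gave 2054 (without PDL2 proliferating replicate 2) to 4068 on leaving out 1 library, and 5098, 208 and 2178 without replicates 1, 2 and 3. PDL1 gave 1095, 0 and 3, and PDL2 3216, 0 and 573. The 11 lists called became 17 with the block, 17 with the block and DESeq2 size factors, 18 with fry and the block, 20 with the block without replicate 3, and 0 with an estimated correlation, with or without the block, or with fry alone. The 46 named genes that passed became 99 with the block, 68 with the block and ligands summed per donor, 12 with a minimum change of 1.5-fold, 25 without both non-proliferating libraries of replicate 1, 0 with ligands summed and no block, 6 to 25 on leaving out any 1 of the 12 libraries, and 0 to 81 on leaving out replicates. A reversal was counted only where the sign changed and the gene passed in at least 1 of the 2 fits compared. By that rule no named gene reversed (4075 values the same, 599 weaker, 138 stronger). Sign changes of genes that passed in neither fit count as the same. The tally covers the alternatives without the block, the block itself and the blocked sums per donor, not the other alternatives of the blocked fits.

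By the same rule, directions of 4 lists reversed. Without both non-proliferating libraries of replicate 1 the list: Cytosolic ribosomal proteins had adjusted p = 3.21e-05 (range over settings 3.07e-06 to 0.99), ribosome biogenesis 0.0239 (0.0239 to 0.993) and the serine list 0.05 (0.05 to 0.993). That omission keeps the proliferating libraries of replicate 1, whose ribosomal protein genes were 2.08 and 2.18 above replicates 2 and 3 on the log2 scale, so this reversal of the ribosomal proteins follows from the unbalanced omission: the same-donor medians of that list were -0.44 to -0.01. The cytokine list had 0.0173 with the replicate block without these libraries and 0.0138 with the block without replicate 1 (0.0138 to 0.993). The cause was not tested for the other lists. The shallowest library had 26914713 gene counts. In data simulated with the same change in every donor, 2-fold changes were recovered in 0% of genes without the block and 50% with it.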

Other observations

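The gene families below and the genes named from them were chosen after the data were seen, and their camera p-values are adjusted over 13 families. Only some of the 13 are described. The adjustment does not account for the choice of families from the same data, so these p-values cannot exclude chance.

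Zinc finger genes of the ZNF series, most of them encoding DNA-binding repressors, were lower in proliferating cells in the mean of both ligands. Of 503 tested 21 fell and 0 rose in edgeR, and with the replicate block 149 fell and 6 rose (median log2 fold change -0.61, camera adjusted p = 6.82e-15, adjusted p = 0.011 with an estimated correlation, and with the block adjusted p = 0.0521 with an estimated correlation). Their median was -0.41 after the trend with length, GC content and expression was taken out. Of 7 guanylate-binding protein genes 3 fell, and 6 with the block (median -1.43, camera adjusted p = 1.25e-08, adjusted p = 0.0114 with an estimated correlation). GBP5, which acts in inflammasome responses, fell from 1583 ± 613 to 510 ± 126 CPM (SD, n = 6, edgeR adjusted p = 0.0396).

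Of 10 HLA class II genes 0 passed in edgeR without the replicate block, and 4 rose with it (median 1.20, camera adjusted p = 0.00244, adjusted p = 0.0749 with an estimated correlation). HLA-DRA, the alpha chain of HLA-DR, was at 38.4 ± 21.4 CPM in proliferating and 8.52 ± 3.36 CPM in non-proliferating libraries (with the block, edgeR adjusted p = 0.000327). Markers of antigen-presenting cells were also measured: LYZ was at 25.5 and 4.82 CPM in proliferating and non-proliferating libraries, CD79B at 37.6 and 17.7 CPM, CD68 at 8.13 and 5.10 CPM, ITGAX at 21.1 and 3.75 CPM, and ITGAM at 24.4 and 4.56 CPM. Others went the other way: LAMP3 and CD83 had log2 fold changes of -2.17 and -0.92. VCAN was lower by mean CPM, at 0.127 and 2.18 CPM, but its fitted log2 fold change was 0.30. Of 20 integrin genes 1 rose and 1 fell, and 8 rose and 2 fell with the block (camera adjusted p = 0.0335, adjusted p = 0.27 with an estimated correlation). ITGA4, a subunit of VLA-4, rose from 183 ± 36.8 to 583 ± 149 CPM (edgeR adjusted p = 0.0232), and ITGA5, a subunit of the fibronectin receptor, fell from 36.9 ± 8.87 to 13.3 ± 3.35 CPM (edgeR adjusted p = 0.0249). Of 16 chemokine receptor genes 1 rose, CCR2, and with the block 7 rose and 4 fell (camera adjusted p = 0.0225, adjusted p = 0.27 with an estimated correlation).

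The 179 named genes were searched for opposite signs in all same-donor differences under the ligands, where single cases can arise by chance. Only IL17F, a cytokine of Th17 cells, had them, with mean same-donor log2 differences of -6.14 under PDL1 and 1.24 under PDL2. Its test of the difference had an edgeR adjusted p = 1, and under PDL1 it was at 14.1 ± 24.4 CPM in proliferating and 93.2 ± 76.5 CPM in non-proliferating libraries.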
